A study of Homo sapiens with 4 samples.

How the data were processed

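The series measured messenger RNA in HCT116, an established human colorectal carcinoma cell line, on 4 one-colour Affymetrix arrays of 54675 probe sets each. Per the labels, total RNA was extracted with Trizol, and biotinylated cRNA was prepared from 2.5 micrograms of it with the manufacturer's 1-cycle kit. Per the labels, cells had been transfected by lipofection with a vector for a non-targeting short hairpin RNA (shCTRL) or for a hairpin RNA against KSR1, and puromycin was used to select clones. There was 1 array for untransfected cells, 1 for shCTRL, 1 for KSR1 hairpin #1 and 1 for KSR1 hairpin #2, and the series design text speaks of single biological replicates. Whether each array came from 1 clone or from a pool of clones is not given in the sources used here.

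The deposited values were intensity values on a linear scale, already summarised to 1 value per probe set and array, and ranged from 4.72 to 26251. The background correction, the summary method and the normalization between arrays that the authors used are not given in the sources used here. The deposited intensity medians of the 4 arrays lay between 50.7 and 52.0 and the 95th percentiles between 1395 and 1441, so the values were used without further scaling. Because they were linear, they were converted as planned for that case to log2(intensity + 16), and every log2 difference below is on that scale, which understates differences of dim probe sets. No detection calls were used, so log2 values under the filter value given below are not told apart from background. On arrays no sequencing depth applies, and the number of arrays limits the precision.

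Probe sets were named through the platform annotation. Of the probe sets, 41097 had 1 gene symbol, 1801 had several and 11777 had none, and genes were named only from probe sets with 1 symbol. Of those, 41043 were matched by gene identifier to a RefSeq gene table of assembly GRCh38.p14, used for names only, and 0 symbols needed an update. A gene took the value of its probe set with the highest mean log2 value over the 4 arrays. Of 19775 genes, the 12468 whose mean reached the median of all probe sets, a log2 value of 6.08, were analysed. No column of values was left unused.

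With 1 array per group, single pairs of arrays were compared by a size rule of 1 log2 unit (2-fold) with no p-value. For KSR1 depletion, a gene had to have both hairpin arrays at least 1 log2 unit above, or at least 1 below, both the untransfected and the shCTRL array. The distance between the nearest arrays of the 2 sides is called the gap. The same rule was applied to the other 2 ways of parting the 4 arrays into pairs. A limma model (lmFit and eBayes, Benjamini-Hochberg adjusted p under 0.05) compared both hairpin arrays with both other arrays with 2 residual degrees of freedom. Its p-values measure the spread between different hairpins and between untransfected and shCTRL cells, and not the spread between cultures of 1 kind, and its standard errors (SE) come from the same fit. Agreement of the hairpins was described by correlations across genes, which are not replicates, with differences that share no control array. Where shCTRL or the untransfected array was shared, the value was set beside 100 simulations of unchanged hairpin arrays.

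Before the data were examined, 25 gene lists with 515 genes were fixed, and 360 of these genes were analysed. They covered KSR and RAS-RAF-MEK-ERK components, ERK pathway output, genes linked to KSR1 in colon cancer, MYC targets, G1/S and G2/M genes, p53 targets, interferon response, unfolded protein and ATF4 response, hypoxia and glycolysis, cholesterol synthesis, oxidative phosphorylation, epithelial junctions and keratins, mesenchymal transition, Wnt targets, intestinal differentiation, inflammatory genes, integrins with matrix and proteases, the BCL2 family with caspases, receptor tyrosine kinases, small RNA machinery, cancer-testis genes, serum response, and markers of fibroblasts and leukocytes. List members without a value here were not analysed here. Each list's median difference was placed among the medians of 10000 random lists of the same size matched on mean expression in 20 bins, as a description of these arrays, and members past limma were also counted adjusted over the list alone.

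Genes named in the text followed a rule fixed before the data were examined. It took KSR1, up to 14 genes with the largest gap in each direction that reached 1 log2 unit, the 6 highest and 6 lowest differences of shCTRL minus untransfected and of hairpin #2 minus hairpin #1, and up to 4 members of each list by the size of the difference between hairpin and other arrays. Genes outside the rule are said to be chosen after their values were seen, which holds for every other list member named. XIST and Y-linked genes were left out of named genes and enter the text as counts only.

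Alternatives covered other filters, the mean over a gene's probe sets, quantile normalization, median centring, other pseudocounts, a 1.5-fold size rule, other variance priors in limma, 3 groups in place of 2 (the same fit as leaving out the untransfected array), and leaving out each array in turn. The methods were tested on simulated data for the comparison of hairpin and other arrays with 200 of the 12468 genes changed. The limma model recovered 100 of 100 genes changed by 1.5 log2 units and 100 of 100 changed by 3 log2 units, with 8 false calls. The size rule recovered 90 of 100 and 100 of 100, with 0 false calls. The simulated noise was normal, with the SD of the gene's expression bin, so genes that vary more than others of their brightness were not covered. In the real arrays EHF, with a difference of 2.03, had a limma adjusted p of 0.67. The recovery therefore does not give the power in these data. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1 were used.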

Results

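Gene expression was measured on 1 array each of untransfected HCT116 cells, cells carrying the non-targeting hairpin shCTRL, and cells carrying KSR1 hairpin #1 or #2. HCT116 is a colorectal carcinoma line, and KSR1 is a scaffold protein that holds the RAF, MEK and ERK kinases together. There were no replicate arrays, so differences between single arrays have no replicate check. The hybridization controls had geometric mean intensities of 2199 in the untransfected, 2286 in the shCTRL, 1902 in the hairpin #1 and 2574 in the hairpin #2 array. The ratio of 3' to 5' actin signal, a sign of RNA integrity, was 2.68, 2.09, 2.01 and 2.22 in the same order, and the ratio for GAPDH lay between 1.14 and 1.19. Markers of other cell types were mostly dim. Of 14 fibroblast markers measured 4 were bright enough to be analysed, among them COL1A1 at log2 8.81 in untransfected cells and 8.68 with hairpin #2, and of 13 leukocyte markers 3 were. The median log2 values over all measured fibroblast markers lay between 5.35 and 5.47, and those over leukocyte markers between 5.46 and 5.64.

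The targeted gene was examined before any other. KSR1 signal was lower with both hairpins on its brightest probe set. Its intensity was 209 in untransfected and 211 in shCTRL cells, against 141 with hairpin #1 and 171 with hairpin #2, which is 33.0% and 18.9% below shCTRL. On the log2 scale the differences from shCTRL were -0.53 and -0.28, and the shCTRL and untransfected arrays differed by 0.01. Genes of this brightness differed between shCTRL and untransfected cells with an SD of 0.34, so only the hairpin #1 difference exceeded that spread. Over both hairpin arrays against both others the log2 difference was -0.40 (SE 0.12, limma adjusted p = 0.67). The other 3 KSR1 probe sets were dim, with intensities between 27.8 and 60.4, and gave no common direction. The paralog KSR2 had intensities of 370, 226, 374 and 224 in untransfected, shCTRL, hairpin #1 and hairpin #2 cells, a pattern that did not follow the KSR1 hairpins.

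**Figure D1:**
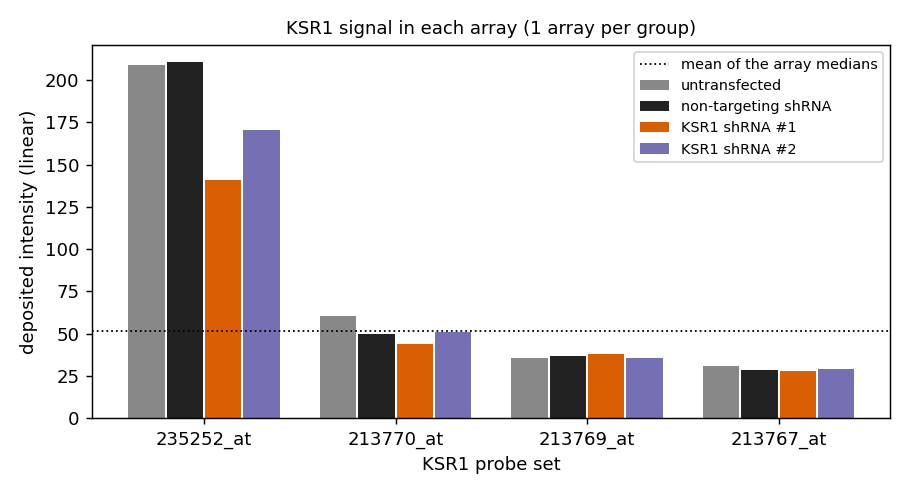
Intensity (linear scale) of the 4 KSR1 probe sets in each of the 4 arrays, with bars starting at 0 and the dotted line at the mean of the array medians. Only the brightest probe set stands well above the line, at 209 and 211 without a KSR1 hairpin and at 141 and 171 with one.

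The central comparison asked which transcripts differ with KSR1 hairpins. The genes that separated both hairpin arrays from both others by at least 2-fold were few, 3 higher and 4 lower. EHF, an epithelial ETS-family transcription factor, was 4.07-fold higher with the hairpins (log2 difference 2.03, SE 0.37). The others were PRKAA2, a catalytic subunit of the energy sensor AMP-activated kinase, and MECOM, a zinc finger transcription factor, both too dim without a KSR1 hairpin for the size of the difference to be given. PRKAA2 lay below the 25th percentile intensity of 18.6 in untransfected cells and at 61.6 in shCTRL, against 221 and 219 with hairpins #1 and #2. MECOM lay at 38.5 and 37.6, below the array medians, against 125 and 139. Lower were ARRDC4, an arrestin-domain gene tied to glucose sensing (-1.60, SE 0.24), the hypoxia-inducible genes NDRG1 (-1.55, SE 0.25) and ANKRD37 (-1.41, SE 0.25), and the glycolytic aldolase ALDOC (-1.40, SE 0.09). The 2 control arrays differed as well, shCTRL minus untransfected being 0.84 for EHF, -0.72 for NDRG1, -0.71 for ANKRD37, 0.27 for ARRDC4 and -0.08 for ALDOC.

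None of these 7 genes passed the test across all genes. The limma comparison called 0 of 12468 genes, with 882 at an unadjusted p under 0.05 and a smallest adjusted p of 0.318. Without any differences, a share of 0.05 of the genes would lie at that unadjusted level. The other pairings of the arrays had 413 and 413 there. They are no baseline for the 882, since differences between hairpin and control arrays add to their residual spread. The size rule gave 7 genes for the hairpin pairing, against 6 when untransfected was paired with hairpin #1 and 18, of which 3 were XIST or Y-linked, when it was paired with hairpin #2, so 1 of the other pairings gave more genes.

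Genes of hypoxia and glycolysis were lower with both hairpins. Of 19 analysed, 17 were below both other arrays in both hairpin arrays, and the median difference was -0.65 log2 units, below all 10000 random lists. With the mean over each gene's probe sets in place of the brightest, that median was -0.37. Besides NDRG1 and ANKRD37, the largest differences belonged to ADM, the vasoactive peptide adrenomedullin (-1.40, SE 0.44), and ANGPTL4, an inhibitor of lipoprotein lipase (-1.35, SE 0.39). Their sizes depended on single arrays. Relative to shCTRL, ADM was at -0.69 with hairpin #1 and -2.01 with hairpin #2, and ANGPTL4 was at -1.02 in shCTRL relative to untransfected cells. Genes of glucose use followed, chosen here after their values were seen: PFKFB4 (-0.99), PDK1 (-0.94), HK2 (-0.85) and the mitophagy gene BNIP3 (-0.82). The list median was -0.59 for hairpin #1 and -0.63 for hairpin #2 against shCTRL, -0.58 and -0.49 against untransfected cells, and -0.02 between shCTRL and untransfected cells. The exceptions were PFKFB3, higher with both hairpins, and the glucose transporter SLC2A1, at log2 10.10 and 10.57 in untransfected and shCTRL cells but 9.58 with hairpin #1 and 11.70 with hairpin #2. By limma, 0 members passed over all genes and 13 passed adjusted over the list alone, with a smallest adjusted p of 0.0104. That count was 3 without the untransfected array and 6 without shCTRL.

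Genes of the ATF4 and unfolded protein response were higher with both hairpins. Of 19 analysed, 11 were above both other arrays and 1 was below, and the median difference was 0.31, above all 10000 random lists. The cystine transporter SLC7A11 was higher by 0.95 (SE 0.21), the glutathione-degrading CHAC1 by 0.86 (SE 0.19), and the serine synthesis enzyme PSAT1 by 0.63 (SE 0.10). DDIT4, an inhibitor of mTORC1 that hypoxia also induces, went the other way at -0.92. The list median was also 0.13 higher in shCTRL than in untransfected cells, above 97.8% of random lists. By limma, 0 members passed over all genes and 4 adjusted over the list alone, with a smallest adjusted p of 0.0312, and 0 passed without the untransfected array, 0 without shCTRL and 1 without hairpin #2.

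Mitotic genes were higher with both hairpins as well. Of 20 G2/M genes, 15 were above both other arrays and 0 were below, with a median difference of 0.28, above all 10000 random lists. Cyclin B1 (CCNB1) was higher by 0.69 (SE 0.16), the mitotic kinase PLK1 by 0.65 (SE 0.18), and the spindle genes HMMR and KIF20A by 0.48 each. All 20 were higher than in shCTRL with either hairpin, while 16 and 17 were higher than in untransfected cells with hairpin #1 and #2. Against shCTRL the list median was 0.28 for hairpin #1 and 0.34 for hairpin #2. Against untransfected cells it was 0.37 for hairpin #2 but 0.14 for hairpin #1, inside the central 95% of random lists (percentile 95.8). Part of the distance lay in shCTRL itself, whose list median was -0.13 relative to untransfected cells and which had the lowest value of the 4 arrays for 14 of the 20 genes. By limma, 0 members passed over all genes and 0 adjusted over the list alone (smallest adjusted p 0.0988). The G1/S list had a median of -0.04, at percentile 1.59 of random lists, with 1 of 20 genes higher and 4 lower with both hairpins, and turned to 0.027 without hairpin #2. It was inside the random range with the mean over probe sets (-0.0049), after quantile normalization (-0.046) and without shCTRL (-0.038).

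**Figure D2:**
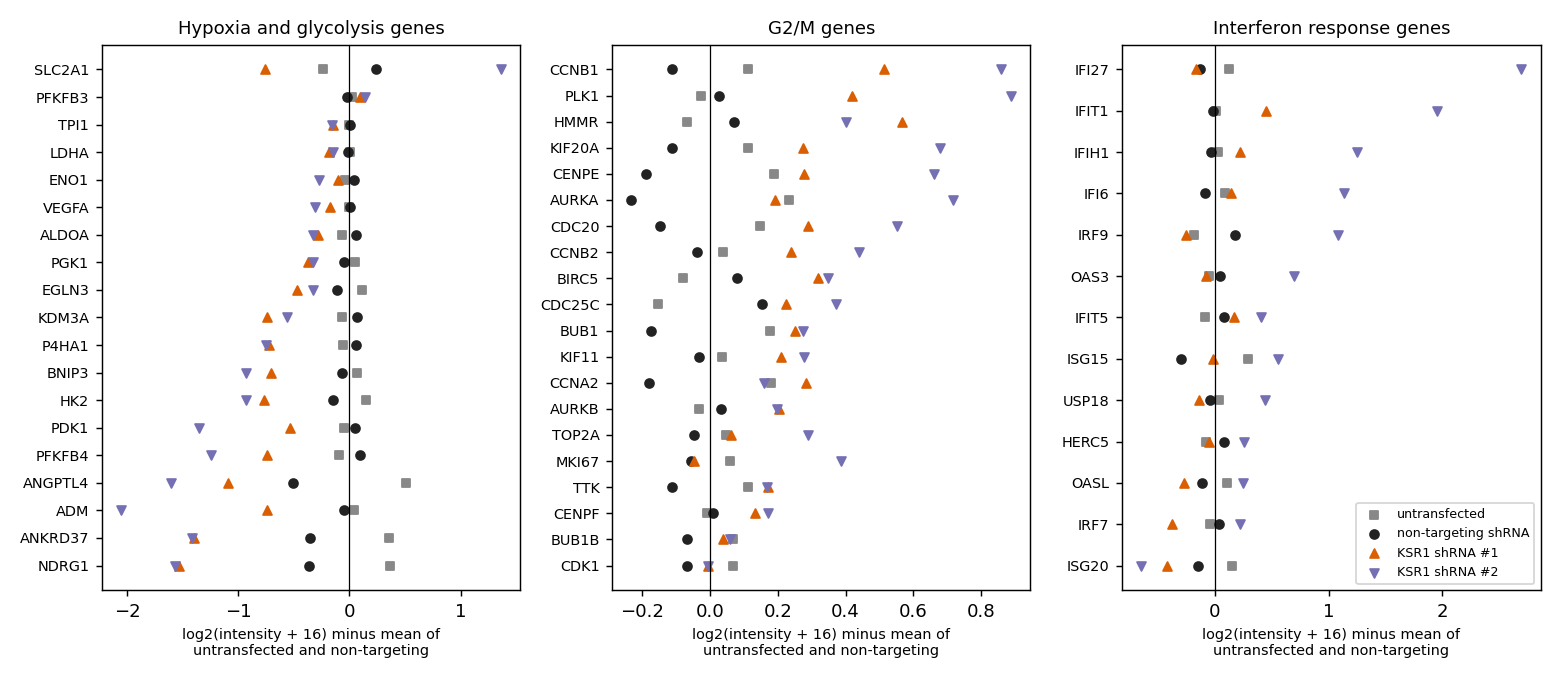
Each point is 1 array's log2(intensity + 16) for 1 gene minus the mean of the untransfected and non-targeting arrays, for the analysed hypoxia and glycolysis, G2/M and interferon genes. Both KSR1 hairpins lie left of both other arrays for 17 of 19 hypoxia genes and right of them for 15 of 20 G2/M genes, while hairpin #2 alone is the highest array for 12 of 13 interferon genes.

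Transcripts that report ERK pathway activity differed in opposite directions depending on the hairpin and the control array. Of 25 ERK output genes, 5 were above both other arrays and 1 was below, and the median was 0.07, within the central 95% of random lists, with a mean of -0.01. Without the untransfected array the median turned to -0.069, at percentile 1.45. DUSP6, a phosphatase induced by ERK, was at log2 10.80 in untransfected cells, 12.51 in shCTRL, 11.56 with hairpin #1 and 11.67 with hairpin #2, so both hairpin arrays lay between the controls. The largest differences between the mean of both hairpin arrays and the mean of the others were those of ETV1 (-0.98), FOSL1 (-0.61) and FOS (0.54), and none passed limma. ETV1 and FOSL1 did not separate the hairpin arrays from both others. Relative to shCTRL they were at 0.19 and 0.02 with hairpin #1 and at -1.10 and -0.70 with hairpin #2. In shCTRL they were also below untransfected cells, at -1.06 and -0.54. The list median was 0.17 higher in shCTRL than in untransfected cells (percentile 99.97). Relative to untransfected cells it was 0.21 with hairpin #1 (percentile 99.99) and 0.09 with hairpin #2, inside the random range. Relative to shCTRL it was 0.03 with hairpin #1, inside that range, and -0.12 with hairpin #2, below it at percentile 0.31. The serum response genes had a median of -0.01, with 3 of 20 higher and 3 lower. KSR and RAS-RAF-MEK-ERK components had a median of 0.03, with 3 of 19 higher and 3 lower, KSR1 among the latter. Genes linked to KSR1 in colon cancer work, PRKAA2 among them, had a median of 0.09, with 2 of 12 higher and 1 lower, which turned to -0.0056 without untransfected cells. MYC targets had a median of 0.07, with 7 of 17 higher and 2 lower, and the median was 0.13 without untransfected cells and 0.16, above the random range at percentile 99.3, without hairpin #2.

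Other metabolic and structural groups were examined in the same way. Cholesterol synthesis genes had a median of 0.13, above 94.5% of random lists, with 9 of 17 higher with both hairpins and 0 lower, led by LSS (0.52), NSDHL (0.52) and SQLE (0.48), and the median was 0.057 without hairpin #2 and 0.081 after quantile normalization. Oxidative phosphorylation genes had a median of 0.04 with 6 of 20 higher and 0 lower. Mesenchymal transition genes had a median of -0.14 with 0 of 7 higher and 1 lower, although the actin-binding TAGLN differed by -1.15. TAGLN was at log2 7.07, 8.22, 6.63 and 6.36 in untransfected, shCTRL, hairpin #1 and hairpin #2 cells, so much of its difference lay in shCTRL. The mesenchymal list median was -0.18, below the random range at percentile 2.15, after quantile normalization and -0.069 without hairpin #2. Receptor tyrosine kinases and ligands had a median of 0.08 with 4 of 22 higher and 5 lower, EGFR among the lower at -0.60 (SE 0.14), and the median turned to -0.080, at percentile 0.3, without hairpin #2. Integrin, matrix and protease genes had a median of -0.09, below the random range at percentile 0.77, but a mean of 0.22, with 2 of 18 higher and 6 lower, and the proteases KLK10 (2.63) and KLK6 (2.12) had the largest differences. The median was inside the range after quantile normalization (-0.077) and without the untransfected array (-0.040), hairpin #1 (-0.060) or hairpin #2 (-0.0039). Inflammatory genes had a median of 0.04, BCL2 family and caspase genes -0.02, intestinal differentiation genes -0.01, small RNA machinery 0.04 and cancer-testis genes 0.11, all within the central 95% of random lists. Fibroblast and leukocyte markers had medians of -0.13 and -0.05.

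**Figure D3:**
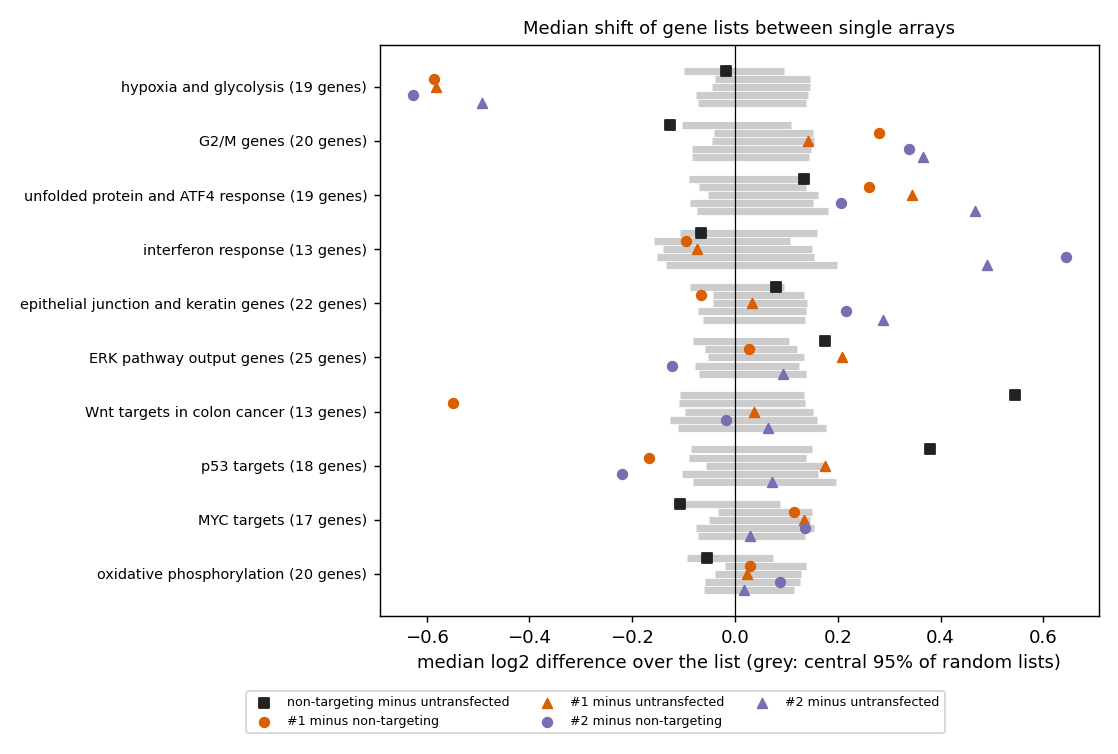
Median log2 difference of 10 gene lists (points) for 5 differences between arrays, with the grey bar giving the central 95% of medians of random lists matched on expression. Hypoxia and glycolysis genes lie below the grey bar for both hairpins against either control array and inside it for shCTRL against untransfected cells.

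The untransfected and shCTRL arrays were compared to show how arrays differ in the absence of a KSR1 hairpin. Vector, transfection, selection, clone, culture and array differ together between them and cannot be told apart. In shCTRL cells 60 genes were at least 2-fold higher and 46 lower. ANXA10, an annexin, was at log2 12.03 in untransfected and 7.81 in shCTRL cells, and the matrix proteoglycan VCAN (-2.98), the acyltransferases GPAT3 (-2.43) and AGPAT4 (-2.13) and the ligand WNT16 (-2.35) were also lower. The carboxypeptidase CPM was at log2 8.44 in untransfected cells and under the filter value of 6.08 in shCTRL. The noncoding VHRT (3.73) and LINC00326 (2.08), the hyaluronan-binding CEMIP (2.69), the transcription factor NFIB (2.04) and the guidance ligand SEMA3A (2.03) were higher, and MAMDC2 was at log2 7.77 in shCTRL and under the filter value in untransfected cells. Of 18 p53 targets, 17 were higher in shCTRL, with a median of 0.38, and GDF15, a stress-induced cytokine, was at log2 10.73 against 11.99. Of 13 Wnt targets, 11 were higher, with a median of 0.54, and SOX9, an intestinal progenitor transcription factor, was at log2 9.78 against 11.29. Both list medians were above all 10000 random lists, and the Wnt median was 0.22 without the filter on dim probe sets. Over the hairpin arrays against both others, the p53 list had a median of -0.04 with 3 of 18 higher and 3 lower, and the Wnt list -0.08 with 0 of 13 higher and 3 lower. Both depended on single arrays, and among all alternatives run, 2 put the p53 list and 3 the Wnt list past the random range. The p53 median was -0.28, at percentile 0, without untransfected cells and 0.10 without shCTRL, and the Wnt median was -0.11, at percentile 1.45, without untransfected cells, -0.15, at percentile 0.1, without hairpin #2, 0.081 without shCTRL and 0.032 without hairpin #1.

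Each KSR1 hairpin was then set against shCTRL alone. With hairpin #1, 14 genes were at least 2-fold higher and 54 lower, and with hairpin #2, 122 were higher and 115 lower. All 13 Wnt targets were lower with hairpin #1 than in shCTRL, with a median of -0.55, and the median was -0.02 with hairpin #2. The p53 targets had medians of -0.17 and -0.22. Against untransfected cells these medians were 0.04 and 0.06 for the Wnt list and 0.18 and 0.07 for the p53 list. Of the genes 2-fold lower, 23 were shared by both hairpins, with 0.498 for independent lists and 17.2 in simulations of unchanged hairpins against the same shCTRL array. Of the higher ones 6 were shared, with 0.137 for independent lists and 16.3 in simulations. The simulated noise was that between shCTRL and untransfected cells. Its 16.3 exceeds the 14 genes that were higher with hairpin #1, so the simulations with a shared array cannot weigh the sharing. With hairpin #1 set against shCTRL and hairpin #2 against untransfected cells, no array was shared. Then 9 lower and 4 higher genes were in common, against 0.533 and 0.181 for independent lists and 0.12 and 0.15 in simulations. Neither baseline allows for genes that vary more between cultures than others do. With untransfected cells and hairpin #2 paired against the others, 12 genes were at least 2-fold higher and 6 lower. The sharing therefore cannot be weighed by these baselines.

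The hairpin arrays were also compared with each other. Between hairpin #2 and hairpin #1, 134 genes were at least 2-fold higher and 80 lower, although the median absolute log2 difference over all genes, 0.13, was the smallest of the 6 pairs of arrays. RUNX2, a transcription factor of bone formation, was under the filter value with hairpin #1 and at log2 10.41 with hairpin #2, and BAMBI, a pseudoreceptor of TGF-beta signalling (4.03), SYTL2 (3.98), ANXA10 (3.64) and KLK10 (3.31) were also higher with hairpin #2. The lipoxygenase ALOX5 was at log2 8.90 with hairpin #2 and under the filter value with hairpin #1. TSPAN5 (-3.88), ARHGAP29 (-3.43) and the ectonucleotidase NT5E (-2.83) were lower with hairpin #2. KLRC3 and NAV3 were at log2 8.10 and 8.49 with hairpin #1 and under the filter value with hairpin #2. Interferon response genes were higher with hairpin #2, by a median of 0.64 over shCTRL, 0.49 over untransfected cells and 0.60 over hairpin #1, and differed by -0.10 between hairpin #1 and shCTRL. Of 22 interferon genes with a value, 13 passed the filter on the mean over the 4 arrays. A gene high with hairpin #2 alone could pass it, which raises these medians. Without the filter on dim probe sets the median over shCTRL was 0.35. IFI27 was at log2 5.95, 5.69 and 5.65 in untransfected, shCTRL and hairpin #1 cells and at 8.51 with hairpin #2, and IFIT1, which binds viral RNA, was at 5.81, 5.78, 6.25 and 7.75. Over both hairpins the list median of 0.29 became -0.08 without hairpin #2, and 4 of 13 genes were higher and 1 lower with both. Epithelial junction and keratin genes had a median of 0.22 over shCTRL with hairpin #2 and -0.07 with hairpin #1, and hairpin #2 was the highest array for 18 of 22. Over both hairpins that list had a median of 0.14, with 7 of 22 higher and 1 lower, and came inside the random range without untransfected (0.11), shCTRL (0.12) or hairpin #2 (0.014).

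Across genes the hairpins' differences were weakly related when no control array was shared. Hairpin #1 minus shCTRL correlated with hairpin #2 minus untransfected with a Pearson r of 0.10 and a Spearman rho of 0.14, and the other pairing of controls gave 0.02 and 0.17, a Pearson r that turned to -0.0036 without a pseudocount. With shCTRL shared, r was 0.42 and the covariance 0.0397, against 0.50 and 0.0377 in simulations of unchanged hairpins, a difference in covariance of 0.00194. With untransfected cells shared, r was 0.46 and the covariance 0.0482 against a simulated 0.0375, a difference of 0.0107. These simulations took their noise from the difference between shCTRL and untransfected cells, so they hold only if the hairpin arrays vary alike.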

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

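The tests of normalization and of single probe sets were chosen before their results were seen, and the tests of RNA degradation, of other splits and of the hairpins were chosen after. Among the analysed genes, 1 was moved by the hairpins at least 1 log2 unit beyond both other arrays in opposite directions. It was the keratin KRT13, named after its values were seen, at log2 7.08 in untransfected, 6.55 in shCTRL, 5.26 in hairpin #1 and 8.18 in hairpin #2 cells. The epithelial junction and keratin list was 0.22 higher with hairpin #2 than in shCTRL and went the opposite way with hairpin #1. For that list, hairpin #2 minus hairpin #1 had a median of 0.23, above all 10000 random lists, which describes these arrays alone. For KRT13 the difference between the hairpins was not tested.

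Hypoxia and glycolysis genes were lower with both hairpins. After quantile normalization or median centring the list median was still -0.63 or further from 0. The deposited arrays were already alike in distribution, so these steps cannot weigh the authors' unknown normalization. Other probe sets, bright enough for 11 of the 19 genes, had a median of -0.31 (bootstrap interval over genes from -0.53 to -0.15). They were lower for 10 genes and higher for 1. Those 11 genes had a median of -0.35 on their brightest probe sets. For them the values argue against a fault of single probe sets as the whole cause. The shCTRL actin ratio of 2.09 lay between those of the hairpin arrays. That is 1 ratio per array, compared after it was seen, and cannot exclude RNA degradation. Culture-to-culture variation, such as density or oxygen at harvest, cannot be told apart from KSR1 loss with 1 culture per group: 1 of the 3 splits gave a median this large, the real one, with 0.04 as the highest other, and 3 splits are too few to reach a share under 0.05. Reduced KSR1 may lower these genes, as a hypothesis that replicate cultures would test.

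Interferon genes were higher in the hairpin #2 array. The 13 analysed, of 22 with a value, passed a filter on the mean that this array alone could carry. With hairpin #1 their median was -0.10 relative to shCTRL, but the KSR1 signals of the hairpins differed by 0.25, within the SD of 0.34 for genes of this brightness, so reduced KSR1 stays open. Other probe sets gave 0.28 over 3 genes with a bootstrap interval from -0.35 to 0.86, too wide to weigh a fault of single probe sets. A response to this hairpin, clone or culture alone stays open too, because the list being at least 0.49 above each of the other 3 arrays is the pattern itself, seen in 1 culture.

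Wnt and p53 targets were lower with hairpin #1 than in shCTRL. Other probe sets, bright enough for 6 of the 13 Wnt genes, had a median of -0.28 and were lower for 6 of 6. Those 6 genes had a median of -0.41 on their brightest probe sets. For them the values argue against a fault of single probe sets as the whole cause. For p53 targets that check was void, with 0.024 over 7 genes whose brightest probe sets had -0.01, so a fault of single probe sets cannot be told apart there. Relative to untransfected cells the medians with hairpin #1 were 0.037 and 0.18, inside the range of random lists. The p53 value lay just under the upper limit, at percentile 97.35, with 15 of 18 genes higher. With hairpin #2 relative to shCTRL the medians were -0.02 for Wnt and -0.22 for p53 targets. The KSR1 hairpin and a raised level in the shCTRL array alone cannot be told apart by these values, since a vector effect shared by all transfected cells and lowered by KSR1 loss would look alike.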

How the results depend on the processing

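The alternatives of the list-member counts and of the Wnt, p53 and interferon shifts between single arrays, and the setting without a pseudocount, were chosen after seeing the data. No paired analysis was possible because each group had 1 array. The limma count was 0 under all 15 alternatives, of which the fit of 3 groups is the same as that without untransfected. With a filter at the 75th percentile, 1 gene was higher with both hairpins, and 57, 36, 133 and 119 genes differed 2-fold for shCTRL against untransfected, hairpin #1 against shCTRL, hairpin #2 against shCTRL and hairpin #2 against hairpin #1, where fewer genes were analysed. With the mean over probe sets these were 1, 62, 42, 153 and 139, and the cause was not tested. At 1.5-fold, 11 genes were higher and 41 lower with both hairpins, and the pairs gave 460, 342, 845 and 701. At that size the hairpin pairing gave 52 genes. The pairing of untransfected with hairpin #1 gave 28, and that with hairpin #2 gave 58, of which 3 were XIST or Y-linked. Leaving out 1 array, which loosens the rule, gave 6 to 77 higher genes and 16 to 53 lower: 6 and 23 without untransfected, 12 and 24 without shCTRL, 77 and 53 without hairpin #1, and 6 and 16 without hairpin #2. For KSR1, the other probe sets, from dimmest to brightest, gave -0.016 and 0.021, 0.036 and -0.027, and -0.13 and 0.033 for hairpin #1 and #2 against shCTRL, so the lower KSR1 signal rests on the brightest probe set, and the others are too dim to decide. Agreement of the hairpins was 0.42 with shCTRL shared, and the other pairing gave 0.059 at the 75th percentile and -0.0036 without a pseudocount. Over 25 lists and 223 alternatives of the hairpin shift, 180 kept sign and side of the random range, 22 changed sign with both values inside it (p53 to 0.10 and Wnt to 0.081 without shCTRL, inflammatory genes to -0.099 without hairpin #2), 10 became weaker, 7 stronger (among them p53 at -0.28 without untransfected, and Wnt at -0.11 without untransfected and -0.15 without hairpin #2) and 4 reversed. The reversed ones were ERK output at -0.069 without untransfected, and G1/S at 0.027, interferon at -0.080 and receptor tyrosine kinases at -0.080 without hairpin #2. Leaving out 1 array, ERK output ranged from -0.069 to 0.082, receptor tyrosine kinases from -0.080 to 0.12, G1/S from -0.080 to 0.027 and interferon from -0.080 to 0.55. Adjusted over the list alone, limma called 3 hypoxia and 0 ATF4 genes with 3 groups. Leaving out 1 array gave 3 to 11 hypoxia genes, 0 to 6 ATF4 genes and 0 to 1 G2/M genes, with 1 residual degree of freedom and the lone array assumed to vary like the others. The hypoxia, G2/M and ATF4 shifts of both hairpin arrays against both others were past the random range under every alternative run, hypoxia at -0.37 with the mean over probe sets.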

Other observations

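The kallikreins, secreted serine proteases encoded in 1 gene cluster, were chosen after their values were seen. Of 11 analysed, 5 were higher with both hairpins than in both other arrays and 1 was lower. KLK10 was at log2 7.53, 8.29, 8.89 and 12.19 in untransfected, shCTRL, hairpin #1 and hairpin #2 cells, KLK6 at 8.07, 8.82, 9.68 and 11.45, and KLK7 at 8.08, 8.03, 8.69 and 11.00. With hairpin #2, KLK8 was 1.43 log2 units above shCTRL, and with hairpin #1 it was 0.16 above it. KLK5, also counted among the 5, was at log2 7.14 with hairpin #2 and under the filter value of 6.08 in the other 3 arrays. Its place above the controls with hairpin #1 is therefore not told apart from background. No test of the cluster as a whole was run.

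Over all analysed genes, 22.5% were higher and 18.4% lower in both hairpin arrays than in both others at any size. Chance gives 16.7% for each direction if the arrays have no array-wide offsets. The untransfected array was the lowest for 30.2% of genes and hairpin #2 the highest for 30.1%, so the excess cannot be told apart from such offsets. The other pairings of the arrays gave 13.6% and 16.6%, and 13.2% and 15.1%. Of the genes that differed 2-fold between 2 arrays, up to 5 per pair were XIST or Y-linked. The identity of the line in each array was not checked beyond such counts, which limits every difference between arrays.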
